A study of Homo sapiens with 6 samples.

How the data were processed

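HCT116 cells, a human colorectal cancer line, were infected with a lentivirus carrying either a short hairpin RNA against CDK5 or a scrambled sequence, and total RNA was hybridised to Agilent 4x44K whole human genome arrays. Each group had 3 arrays, 1 per sample. Groups were taken from the treatment tag of each sample. The titles give the same groups, whereas the free-text descriptions name the opposite condition for every sample, so CDK5 itself was examined first as a check of the labels. The labels do not say whether the 3 replicates came from separate infections or cultures, so the p-values measure the spread between these arrays, which may be technical.

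Per the labels' protocols, RNA was amplified and labelled with Cy3 in a one-color procedure. The deposited scanner files hold spot intensity read with Agilent Feature Extraction 10.7.3.1, per the file headers. Its processed intensity is background-subtracted and detrended within an array and is not normalized between arrays. The authors also deposited a table of log2 values for the same arrays, of which the making is not given in the sources used here. Every column of that log2 table had a median of 6.66 and the same quartiles, and each correlated with the log2 intensity of its own array at r between 0.9993 and 0.99996 across probes. Differences between arrays ran the same way in both sources (r from 0.979 to 0.989), so its scale is log2, its direction is that of the intensity and genes were not centred. Its between-array normalization stays unknown beyond the equal quartiles. The authors' table served only as an alternative. With it 8894 genes changed, against 8922 with quantile normalization, so these alternatives may not be separate checks.

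Each array held 43376 non-control spots for 41000 probes. Between 85 and 141 spots per array were flagged as outliers and left out, and 0 spots were saturated. The processed intensity was put on the log2 scale, the 75th percentile of the array's non-control spots was subtracted, and spots of one probe were averaged. A probe was named through its accession in a RefSeq table of assembly GRCh38.p14 (27429 probes), otherwise through its symbol (2279) or an older symbol (436), and 172 probes kept the name in the file. The remaining 10684 probes were not named and were not tested as genes. Of 19042 named genes, 8009 had more than 1 probe. Probes well above background on all 3 arrays of at least 1 group were kept. Of the kept probes of a gene, that with the highest mean over the 6 arrays stood for it, which left 13749 genes tested. Probe positions are on hg19, the build per the file headers.

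Knockdown was compared with scramble in limma 3.58.1 (lmFit and eBayes, two-sided) under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are knockdown minus scramble on the log2 scale, given with the standard error (SE) of the fit. Where a gene was not well above background on any array of one group, only a bound is given. The bound sets the bright group's mean against the mean, per array of the dim group, of the higher of its own signal and the lowest signal of any probe well above background. Before the data were examined, 38 gene lists were written for pathways, complexes and markers of other cell types, and 37 of them had at least 5 genes tested. These lists were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists. Of 1120 listed entries, 972 were tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

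The genes named were fixed by rule before the data were examined. They are CDK5, then the 12 largest increases and 12 largest decreases among named genes that passed the test, were well above background on all 6 arrays and did not overlap between groups. The 3 genes per direction with the largest bound follow, then up to 4 members per described list by smallest adjusted p, and every passing member of the CDK5 partner and AP-1 lists. A gene with another probe changed in the opposite direction is named as uncertain. Exceptions were also made that the rule did not provide for. Where 5 or fewer members of a list changed in one direction they are named too, as are 3 interferon genes, and these were chosen after their values were seen. Some genes that the rule or its exceptions would name are not reported here.

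The arrays were spread over 2 slides, each scanned separately. The slide with the 3 scramble arrays also held knockdown replicate 1, and knockdown replicates 2 and 3 were on the other slide. Results were therefore recomputed with slide as a block and within the slide holding both groups, which both rest on knockdown replicate 1 for the difference. Other alternatives were background correction by normexp, other scalings and filters, other ways to combine probes, slide as a random block, replicate number as a block, other tests, the authors' table, and leaving out each array. Precision is limited by the number of arrays.

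The fit and the list test were tested on simulated data with the means and within-group SDs of 13730 genes, 3 arrays per group, and 200 genes changed by known sizes. Of the genes changed by 1.19-fold, 38% were recovered in the right direction. The shares were 82% at 1.41-fold, 88% at 2-fold and 98% at 4-fold. Unchanged genes made up 4.28% of the calls, and the 1 list shifted by 0.5 was the 1 list called. Noise was drawn independently for each gene, so the simulation does not test list calls among genes that vary together. It also changed far fewer genes than were called in the real comparison.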

Results

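Gene expression was measured in HCT116 cells, an established human colorectal cancer line, after lentiviral delivery of a CDK5 short hairpin RNA (3 arrays) or a scrambled sequence (3 arrays). CDK5 is a cyclin-dependent kinase that is activated by p35 and p39 and is best known for its role in neurons. The comparison asks which transcripts differ in cancer cells once CDK5 is depleted. Between 64.8% and 67.0% of non-control spots were well above background on each array, and the 75th percentile of the processed signal lay between 760.8 and 872.2.

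CDK5 was strongly depleted in the samples tagged as knockdown. Its 1 probe (A_23_P8400, hg19 chromosome 7, 150751330 to 150751501) read 1.41, 1.41 and 1.45 in scramble replicates 1 to 3, as log2 signal relative to the array's 75th percentile. In knockdown replicates 1 to 3 it read -2.72, -2.47 and -2.47. The group means were 1.42 ± 0.03 (SD, n = 3) and -2.55 ± 0.15 (SD, n = 3), a difference of -3.98 (SE 0.075), so that 6.36% of the scramble signal was left. limma gave an adjusted p of 2.09e-06, and an exact two-sided permutation test gave p = 0.1, the smallest possible with 3 against 3. The signal follows the treatment tags and titles and goes against the free-text descriptions. With slide as a block, or within the slide that held both groups, the difference was -4.14.

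A large part of the transcriptome shifted, mostly by small amounts. Of 13749 genes tested, 9079 (66.0%) changed at an adjusted p under 0.05 in limma, 4799 higher and 4280 lower in knockdown. Of the changed genes, 77.3% differed by less than 1.5-fold, and 648 differed by at least 2-fold, 380 higher and 268 lower. The groups did not overlap in 72.3% of genes, where chance gives 10%. Arrays correlated across genes at 0.9956 to 0.9971 within a group and at 0.979 to 0.982 between groups. The median within-group SD was 0.047 in scramble and 0.052 in knockdown. With slide as a block 7464 genes changed, and within the shared slide 7030. Scaling to the median instead of the 75th percentile moved the median of all genes by -0.107, so that 3197 genes were higher and 5333 lower.

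Among genes well above background on all 6 arrays, the largest increases included the interferon-induced genes IFIT1, IFI27 and IFI6 and the transcription factor GRHL3. IFIT1, an interferon-induced antiviral protein, rose by 3.51 (SE 0.075, 11.4-fold, adjusted p = 2.45e-06 in limma). The interferon-induced IFI27 and IFI6 rose by 3.19 and 2.90, and the antiviral cytidine deaminase APOBEC3G by 2.25. The epithelial transcription factors GRHL3 and EHF were higher by 3.48 and 2.25. SCG2, a secretogranin of neuroendocrine granules, was higher by 3.01, and ANXA10, an annexin of gastric epithelium, by 2.34. KRTAP3-1 was higher by 3.21, SAMD11 by 3.08, the helix-loop-helix inhibitor ID3 by 2.28 (SE 0.203) and CAPN6 by 2.25.

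Among the same genes, the largest decrease after CDK5 was in TNFRSF6B, a decoy receptor for FAS ligand, at -2.99 (SE 0.041, 7.96-fold lower, adjusted p = 1.44e-06 in limma). The calcium-binding protein CALB2 followed at -2.78, LEMD1 at -2.71 and the membrane protein EMP1 at -2.49. LY6K differed by -2.48, ANKRD22 by -2.46, the water and glycerol channel AQP3 by -2.41 and the phosphodiesterase PDE2A by -2.34. The hyaluronan synthase HAS3 differed by -2.32, the phosphatase inhibitor PPP1R14C by -2.18 and NT5E, the ectonucleotidase CD73, by -2.15. B2M, the light chain of HLA class I molecules and a common reference gene, was 4.09-fold lower (-2.03, SE 0.034). A second B2M probe, designed on a clone sequence per the file annotation, gave -0.14 (SE 0.153, adjusted p = 0.48 over all probes). Its signal was low, at log2 means of -3.18 in scramble and -3.32 in knockdown relative to the 75th percentile, though well above background on all 6 arrays.

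**Figure D1:**
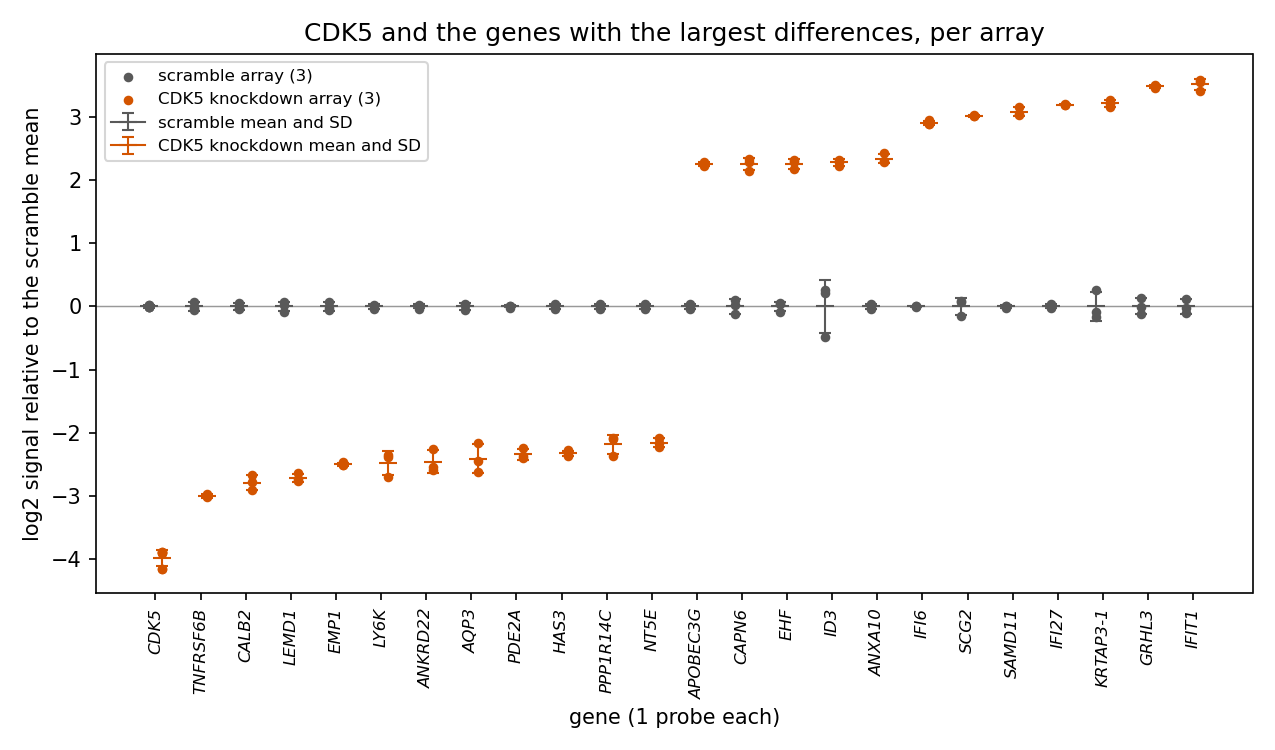
Log2 signal of CDK5 and of the genes with the largest differences among those well above background on all 6 arrays (x axis), relative to the scramble mean (y axis, log2). Points are arrays and bars show mean and SD of 3 scramble or 3 CDK5 knockdown arrays. CDK5 lies lowest, at -3.98, and IFIT1 highest, at 3.51. Genes besides CDK5 were shown only if they passed the test and the groups did not overlap.

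Other genes were well above background in 1 group alone, 83 in knockdown and 47 in scramble. TGFBI, an extracellular matrix protein induced by TGF-beta, was at least 12.4-fold higher in knockdown (adjusted p = 0.000468 in limma). VTCN1, the immune checkpoint ligand B7-H4, was at least 5.71-fold higher and the zinc finger gene ZNF155 at least 5.0-fold higher. RPS4Y2 and RPS4Y1, Y-linked ribosomal protein genes, were at least 6.47-fold and 6.38-fold lower. Their sequences are near-identical, so which of them the probes measured is uncertain. Both probes were well above background on 3 scramble and 0 knockdown arrays. The cause was not tested, so a response of these genes to CDK5 depletion is not shown. CORO2B was at least 3.20-fold lower.

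Interferon-stimulated genes rose as a group. Of 37 tested, 31 were higher and 1, HERC5 (-0.23), was lower, with a median of 1.27 and 23 members at least 2-fold higher. Adjusted over the list alone, 32 were higher and 1 lower. HERC5 was at -0.20 and not past the test with slide as a block or within the shared slide, where 30 members were higher. Beside IFI27 and IFI6, IRF9, the DNA-binding subunit of the interferon-activated complex ISGF3, rose by 2.25 (SE 0.031) and SAMD9 by 2.05 (SE 0.030). camera gave an adjusted p of 4.84e-11, and adjusted p = 0.28 with an estimated correlation.

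Mitotic genes were higher and DNA replication genes lower. In the list of G2/M and mitotic genes, 41 of 55 were higher, among them CDCA3 (0.69, SE 0.025) and KIF18A (0.63, SE 0.032). CDK1, MAD2L1, CEP55, ANLN and SPC25 were lower, by -0.35 to -0.42 for the first 3 and by -0.18 and -0.15 for the others. Neither ANLN (-0.13) nor SPC25 (-0.081) passed the test with slide as a block or within the shared slide. The list had a median of 0.21, and 42 members were higher and 5 lower when adjusted over the list alone. Median scaling, which moved the median of all genes by -0.107, left 22 members higher and 7 lower, with a median of 0.105. camera still called the list there (adjusted p = 0.000309). camera gave an adjusted p of 3.42e-05, and adjusted p = 0.37 with an estimated correlation. In the G1/S and DNA replication list, 32 of 48 were lower and 5 higher, with a median of -0.20, and 33 were lower and 5 higher when adjusted over the list alone. UHRF1, which maintains DNA methylation, fell by 1.16 on the log2 scale (SE 0.049), the helicase subunit MCM3 by 0.90 and cyclin E1 (CCNE1) by 0.64. Members that were higher included the helicase subunits MCM6, MCM5 and MCM2, by 0.76, 0.13 and 0.19, and E2F7, by 0.35. MCM5 (0.11) was not past the test with slide as a block or within the shared slide, and MCM2 (0.24) not with slide as a block. camera gave an adjusted p of 3.26e-05, and adjusted p = 0.37 with an estimated correlation.

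Targets of ATF4, the transcription factor of the amino acid stress response, fell together. Of 32 tested, 30 were lower and 1, the cystathionine synthase CBS (1.90, SE 0.149), was higher, with a median of -0.54 and the same counts when adjusted over the list alone. ASNS, the asparagine synthetase, fell by 1.88 on the log2 scale (SE 0.026), the transcription factor CEBPB by 1.04, the serine pathway enzyme PSAT1 by 1.00 and the mitochondrial folate enzyme MTHFD2 by 0.90. camera gave an adjusted p of 3.03e-10, and adjusted p = 0.058 with an estimated correlation.

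Genes of ERK1/2 feedback and the immediate-early response were lower in 22 of 27 cases and higher in 1, EPHA4 (0.30), with a median of -0.52. Adjusted over the list alone, 23 were lower and 1 higher. The ERK phosphatases DUSP5 and DUSP4 fell by 1.98 (SE 0.034) and 0.81 (SE 0.040) on the log2 scale, the zinc finger factor EGR1 by 1.46 and IER2 by 0.78. camera gave an adjusted p of 4.73e-06, and adjusted p = 0.28 with an estimated correlation. YAP/TAZ targets were lower in 13 of 18 cases and higher in 1, AJUBA (0.32), with a median of -0.29 and the same counts adjusted over the list alone. The matricellular protein CCN1 differed by -1.13 (SE 0.048) and GADD45B by -0.79, beside NT5E at -2.15. For this list camera gave an adjusted p of 0.00379, and adjusted p = 0.28 with an estimated correlation.

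Ribosomal and respiratory chain genes shifted down by small amounts that depended on the normalization. Of 75 cytosolic ribosomal protein genes, 69 were lower and 0 higher, with a median of -0.28, and 70 were lower when adjusted over the list alone. RPL9 differed by -0.56 (SE 0.036), RPL26 by -0.39 and RPL30 by -0.34. camera gave an adjusted p of 1.66e-12, and adjusted p = 0.37 with an estimated correlation. With quantile normalization the median of the ribosomal protein genes was -0.074, with 31 lower and 3 higher (camera adjusted p = 0.0076), and in the authors' table it was -0.081, with 32 lower and 1 higher. Among oxidative phosphorylation genes 41 of 60 were lower and 6 higher, with a median of -0.18, and 42 were lower and 6 higher when adjusted over the list alone. NDUFB6 of complex I differed by -0.47 (SE 0.025), SDHD of complex II by -0.55 and UQCRC2 of complex III by -0.49. camera gave an adjusted p of 3.26e-05, and adjusted p = 0.27 with an estimated correlation. With quantile normalization the median of this list was -0.048, with 21 lower and 14 higher.

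Ribosome biogenesis and MYC target genes were lower in 19 of 32 cases, with a median of -0.17 and the same counts adjusted over the list alone. DDX21 differed by -0.48 (SE 0.024), NOP16 by -0.42 and MYC by -0.76, the last uncertain because another probe went the opposite way. ODC1 (0.49), PPAN (0.37), SRM (0.29), CAD (0.29) and NOP2 (0.17) were higher. camera gave an adjusted p of 0.00589, and adjusted p = 0.37 with an estimated correlation. Cholesterol biosynthesis genes were lower in 13 of 25 cases, with a median of -0.14 and the same counts adjusted over the list alone. The sterol demethylase CYP51A1 differed by -0.65 (SE 0.032), IDI1 by -0.60 and the sterol sensor partner INSIG1 by -0.58, while STARD4 (0.23) and HSD17B7 (0.16) were higher, the latter not past the test with slide as a block (0.20). For cholesterol genes camera gave an adjusted p of 0.0184, and adjusted p = 0.47 with an estimated correlation. With quantile normalization camera gave adjusted p values of 0.18 for the oxidative phosphorylation, 0.14 for the ribosome biogenesis and 0.059 for the cholesterol list, and with the authors' values it gave 0.16, 0.12 and 0.058.

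Hypoxia-induced and glycolysis genes were higher in 20 of 35 cases, with a median of 0.24, and 21 were higher and 5 lower when adjusted over the list alone. With median scaling 15 were higher and 7 lower, with a median of 0.131 (camera adjusted p = 0.0174). The glucose transporter SLC2A1 was higher by 1.21 (SE 0.030), PFKFB4 by 0.96 and the oxygen-sensing hydroxylase EGLN3 by 0.84. Classical hypoxia targets were also among the 5 lower members, the carbonic anhydrase CA12 at -1.58 and VEGFA at -1.11, with PFKP at -0.29 and ANGPTL4 at -0.12. GAPDH was at -0.15 and turned to 0.072 with quantile normalization and 0.067 in the authors' table, neither past the test. ANGPTL4 (-0.13) and GAPDH (-0.073) did not pass with slide as a block or within the shared slide. camera gave an adjusted p of 0.0184, and adjusted p = 0.37 with an estimated correlation.

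**Figure D2:**
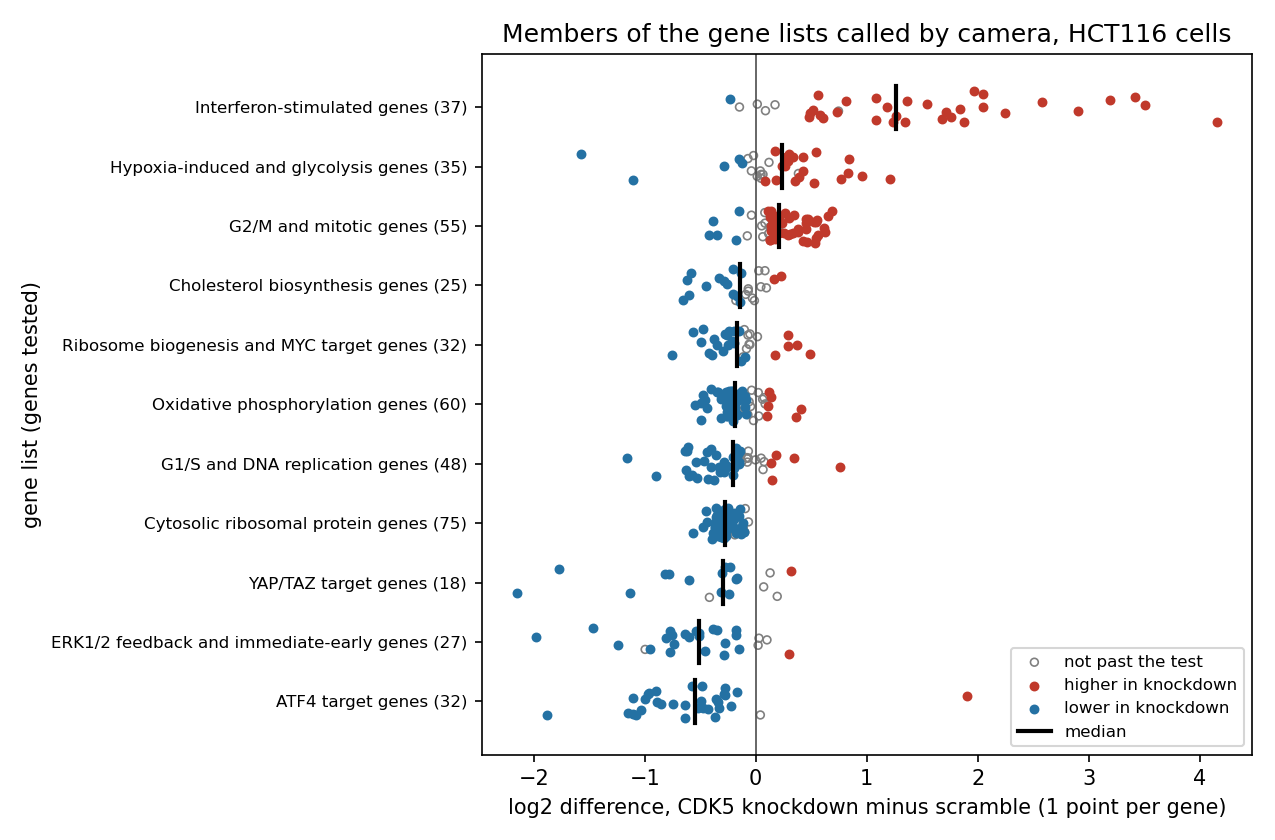
Log2 difference, knockdown minus scramble (x axis), of each member of the 11 gene lists called by camera with its preset correlation (y axis, number of genes tested in brackets). Filled points passed the test (red higher, blue lower in knockdown), open points did not, and black bars mark medians, from 1.27 for interferon-stimulated genes to -0.54 for ATF4 targets.

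AP-1 factors and the ERK5 cascade were listed because published work on CDK5 in colorectal cancer has addressed them. Of 18 AP-1 subunits tested, 9 were lower and 6 higher, also when adjusted over the list alone, with a median of -0.30, and camera did not call the list (adjusted p = 0.14). JUN fell by 1.38 on the log2 scale (SE 0.034, adjusted p = 3.37e-06 in limma), JDP2 by 1.35, FOSL1 by 1.24, FOS by 0.92, MAFF by 0.91 and MAFG by 0.86. JUNB differed by -0.53, JUND by -0.52 and ATF3 by -0.52. Higher members included BATF2, by 0.71, FOSL2 by 0.40, BATF3 by 0.39, MAFK by 0.34 and ATF2 by 0.11, the last within the shift of -0.107 that median scaling gives to all genes (-0.00098 there). With slide as a block and within the shared slide, FOSL2 (0.20) and MAFK (0.11) were not past the test, nor was ATF2 (0.14) within the shared slide. In the ERK5 and MEF2 list, 5 of 12 were higher and 5 lower (camera adjusted p = 0.72), with 5 higher and 6 lower when adjusted over the list alone. ERK5 itself (MAPK7) was higher by 0.43 and its kinase MAP2K5 by 0.75, and MEF2C by 1.45, NR4A3 by 0.79 and MAP3K2 by 0.17. SGK1 differed by -1.43, KLF4 by -1.27, KLF2 by -0.59, NR4A1 by -0.59 and MAP3K3 by -0.35. MAP3K2 (0.18) was not past the test within the shared slide.

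Activators and binding partners of CDK5 moved both ways, 6 of 14 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.99). CDK5RAP3 was higher by 0.47, CDK5RAP1 by 0.44, CDK16 by 0.34, CDK5R2, the activator p39, by 0.30, CDK5RAP2 by 0.25 and DPYSL2 by 0.20. LMTK2 differed by -0.96, NES by -0.47, cyclin D1 (CCND1) by -0.27, CABLES1 by -0.21 and CCNI by -0.14. DPYSL2 (0.21) and CCNI (-0.12) did not pass the test with slide as a block or within the shared slide.

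Of the 37 lists, camera with the preset correlation called 11, 3 upward and 8 downward, and camera with an estimated correlation called 0 (5 had an unadjusted p under 0.05), while fry called 34. With slide as a block or within the shared slide 11 lists were also called, where the difference rests on 1 knockdown array and, within the shared slide, the spread on the scramble arrays alone. There, mean differences relative to other genes were 1.38 for interferon-stimulated genes, 0.23 for mitotic genes and 0.16 for hypoxia genes. They were -0.61 for ATF4 targets, -0.58 for ERK1/2 feedback, -0.53 for YAP/TAZ, -0.29 for ribosomal proteins, -0.25 for G1/S, -0.22 for cholesterol, -0.18 for oxidative phosphorylation and -0.17 for ribosome biogenesis genes.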

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

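Tests of the slide were chosen after per-array values of some list members had been seen; the other tests were set beforehand. Probes without a gene name were not part of the gene comparison and also changed. Of 5133 such probes tested, 1434 were higher and 1350 lower, and 190 were at least 2-fold higher and 53 at least 2-fold lower in knockdown, a signal in data outside the comparison above. Among those past the test and well above background on all 6 arrays, the largest increases were in A_32_P225021 (2.43) and A_24_P229884 (2.37). The largest decreases among them were in A_23_P143102 (-2.62) and A_32_P103966 (-2.13).

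The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9079 changed genes, 4799 higher, 4280 lower and 648 at 2-fold or more, while the highest of the other splits gave 0 in each case, so 1 of 10 splits reached each count. For gene lists, 2 of the 10 splits, the real one included, gave as many, since the real split called 11 and the highest other also called 11. The other splits called between 6 and 11 lists, although limma called 0 genes in each of them, with 35 to 259 genes at an unadjusted p under 0.05. Each of the other splits puts 2 arrays of one group and 1 of the other on a side and so carries part of the real difference. That difference adds to the spread within each side, which works against calling genes there. Neither the gene counts nor the list counts of the other splits are therefore values without an effect.

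Interferon-stimulated genes were higher in knockdown, with 31 of 37 members past the test. A slide or scan difference as the whole cause is argued against by a mean shift of 1.38 relative to other genes on the slide that held both groups, from 1 knockdown array, where single scramble arrays lay at -0.034 to 0.056. Induced interferon transcripts remain a candidate explanation. Of 15 interferon ligand probes on the array, 3 were higher and well above background on all 3 knockdown arrays. IFNE was at least 3.38-fold higher, IFNL2 higher by 1.02 and IFNA4 by 0.60. IFNA4 was not past the test with slide as a block or within the shared slide, where it was at 0.32. IFNL2 and IFNA4 have near-identical relatives. IFNL1 was also higher, but well above background on 0 scramble arrays and only 1 of 3 knockdown arrays, so no size is given. Most of the other probes, that of IFNB1 among them, were well above background on 0 arrays, so their change is not known. Sensing of hairpin RNA and a consequence of CDK5 depletion may each underlie the rise of interferon-stimulated genes, and 1 hairpin against 1 control does not separate them. The Y-linked RPS4Y1 and RPS4Y2 also differed between the groups. Whether the cell populations differed for reasons other than CDK5 depletion was not tested, so that stays open too.

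Ribosomal protein genes were lower in knockdown, with a median of -0.28. Compression of bright signals as the whole cause is argued against by 10000 lists matched on mean signal, of which the median was -0.089, the 5th percentile -0.149 and the lowest -0.217. Each match came from the 50 other genes nearest in signal, and how near these lay for the brightest ribosomal genes was not tested. The matches were drawn independently, so the spread of the medians may be too narrow for genes that vary together. Much of the shift may still be shared with other bright genes, since quantile normalization, which evens out such trends, left a median of -0.074. Reference genes, not called by camera (adjusted p = 0.13), had a median of -0.23, with 10 of 16 lower and 5 higher. With quantile normalization the median of the reference genes was -0.0027. A slide or scan difference as the whole cause is argued against, at the scaling reported, by a mean shift of -0.288 on the slide that held both groups, from 1 knockdown array, where single scramble arrays lay at -0.026 to 0.046. A biological difference between the groups stays open as a hypothesis, and the growth state of the cultures was not tested.

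B2M, itself inducible by interferon, was lower while interferon-stimulated genes were higher. A common fall of class I antigen presentation genes is argued against by 12 measured genes of this pathway, of which 8 were higher and 0 lower, with a median of 0.23. A fault of 1 probe stays open, since the other B2M probe, on hg19 chromosome 15, was at -0.14 (SE 0.153). That probe was dim (log2 means of -3.18 and -3.32) and designed on a clone sequence rather than the reference transcript, per the file annotation, so the pair may measure different transcripts. An off-target match of the hairpin to B2M was not tested.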

How the results depend on the processing

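One alternative, normexp with outlying local backgrounds replaced, was chosen after seeing the data. Planned normexp correction left 7 changed genes in limma, 0 higher (1108 at an unadjusted p under 0.05) and 7 lower, 7 at 2-fold or more, and CDK5 at -2.32 (adjusted p = 0.14, against 1.12e-08 to 0.00276 under its other alternatives). On 3 arrays 7, 9 and 17 spots had a local background over 100, up to 65228, and the fitted background mean was -193, -1136 and -1274, against -2.55 to -4.15 on the others. With those backgrounds replaced by the array median, 8639 genes changed, CDK5 was at -3.50 and 293 genes differed by 2-fold or more. This setting adds an offset of 50 to every spot, which shrinks differences of dim genes by construction. Planned normexp reversed RPS4Y1 (0.37), RPS4Y2 (0.29), CORO2B (0.92), CD68 (0.34), CCN2 (0.79), SNAI2 (1.17), ZEB1 (0.96), LMTK2 (0.49), NES (0.60), FOS (0.38), FSTL3 (0.37), ATF2 (-0.13), CDK5RAP2 (-0.068), CDK5RAP3 (-0.074), DPYSL2 (-0.23), E2F7 (-0.15), MCM2 (-0.38), MCM5 (-0.36), CAD (-0.097), NOP2 (-0.11), ODC1 (-0.17) and SRM (-0.14), none past the test. It also turned the medians of the mitotic (-0.24) and hypoxia (-0.37) lists and ended their calls and that of the YAP/TAZ list (camera adjusted p = 0.23, 0.40 and 0.079). Of the other lists described, it turned the medians of AP-1 subunits (0.12), CDK5 partners (0.14), p53 targets (-0.067) and leukocyte markers (0.91), and it called 5 lists that are not among the 11, namely histone (adjusted p = 0.00295), protease and integrin (0.0288), embryonic kidney (0.0434), focal adhesion (0.0016) and reference genes (0.00487). Outside the 11, other settings called the small RNA pathway list 7 times (0.0253 to 0.0464, 0.0515 as reported), the heat shock list 2 times (0.0354 and 0.0382), the protease and integrin list 2 times (0.0277 and 0.0382), and the reference (0.0341), focal adhesion (0.0382) and DNA repair (0.0341) lists once each. Elsewhere, GAPDH turned to 0.072 (quantile) and 0.067 (the authors' table); the cause was not tested. Median scaling put ATF2 at -0.00098 and gave 3197 genes higher, its own shift of -0.107 of all genes being the cause of both.

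Under the remaining alternatives counts of genes stayed within 1.5 times those reported. For lists, camera with an estimated correlation gave 0 (5 at an unadjusted p under 0.05) and fry, which does not compare a list with other genes, gave 34. Lists with slide as a random block were not run, because camera takes no block. The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at 0.060, -0.030 and 0.053, and the replicate block gave 8698 changed genes. Leaving out each array gave 8161 to 9109 changed genes, 636 to 701 at 2-fold, 11 to 12 lists, and CDK5 at -4.02 to -3.89. Of 152 other named genes, 130 had the same direction and call under every setting but planned normexp. With slide as a block 16 lost their call and within the shared slide 16, 18 in either, with adjusted p from 0.0534 to 0.367. These were ANGPTL4, ANLN, ATF2, CCNI, DPYSL2, FOSL2, GAPDH, HERC5, HSD17B7, IFNA4, KLF10, LTBP3, MAFK, MAP3K2, MCM2, MCM5, SPC25 and ZEB1. EPHA4, FOSL1, NES and NOP2 lost it only under other settings. Calls ended for 11, 4 and 8 named genes without scramble replicate 1, 2 or 3, and for 6, 4 and 9 without knockdown replicate 1, 2 or 3, with adjusted p from 0.0501 to 0.128; these were ANGPTL4, ATF2, DPYSL2, FOSL2, GAPDH, HSD17B7, LTBP3, MAFK, MCM2, NES and SPC25.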

Other observations

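Lists that camera did not call also held large changes in both directions. Of 36 p53 targets tested, 20 were higher and 10 lower (camera adjusted p = 0.21). The oxidoreductase gene TP53I3 was higher by 1.70 (SE 0.036), while the stress cytokine GDF15 was at -1.31 and the BH3-only gene PMAIP1 at -0.92. Among 22 TGF-beta targets, 12 were higher and 5 lower (camera adjusted p = 0.13). The inhibitory SMAD7 was higher by 1.87 (SE 0.033) and the decoy receptor BAMBI by 1.17. CCN1 (-1.13), FSTL3 (-0.22), KLF10 (-0.13), LTBP3 (-0.12) and CCN2 (-1.77, well above background on 2 of 3 knockdown arrays) were lower. KLF10 (-0.11) and LTBP3 (-0.14) did not pass the test with slide as a block or within the shared slide. Of 18 Wnt targets, 7 were higher and 6 lower, with CEMIP at 1.92, BMP4 at 1.41, DKK1 at -1.12 and CD44 at -0.88. For this list camera took the 17 genes with a value on every array and gave an adjusted p of 0.69.

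Of 13 mesenchymal genes tested, 4 were higher and 3 lower. The smooth muscle actin gene ACTA2 was higher by 1.33, SPARC by 1.20, FN1 by 1.15 and TAGLN by 0.88. SNAI1 was lower (-0.41) and ZEB1 at least 1.92-fold lower, and camera did not call the list (adjusted p = 0.53). The probe of SNAI2 was lower, and was well above background on 3 scramble and 0 knockdown arrays. Another SNAI2 probe was well above background on a knockdown array, so the rule for bounds did not apply and no fold is given. ZEB1 was not past the test with slide as a block or within the shared slide. Among 24 protease, plasminogen and integrin genes, 8 were higher and 14 lower (camera adjusted p = 0.098), with ITGB8 at 1.70, ITGA6 at -1.14, ITGA3 at -1.11 and PLAU at -0.74. Of 27 histone genes, 9 were higher and 11 lower, with a median of -0.098 and a mean of 0.052, and camera did not call them (adjusted p = 0.68). H2AC6 was higher by 1.82 and H2BC12 by 1.03, both uncertain because histone genes are near-identical.

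Few markers of other cell types were tested, and their lists did not all move the same way. Of 17 leukocyte markers, 8 were tested, 3 higher and 3 lower. CD68, a lysosomal glycoprotein, had the largest difference of the 8, at -2.71, and was well above background on 1 of 3 knockdown arrays. Of 15 fibroblast and endothelial markers 3 were tested, 1 higher and 0 lower, too few for camera. Of 11 embryonic kidney markers 5 were tested, 3 higher and 0 lower (camera adjusted p = 0.40). In 303 genes, probes well above background on all 6 arrays changed in both directions, in 7 of them by at least 1.5-fold each way.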
